A study of Sus scrofa with 2 samples.

How the data were processed

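The data were 2 two-colour arrays of the porcine brain library microarray, a spotted array of cDNA clones. Each array compared whole brain with whole brain: per the labels, 18 µg of total RNA from the brain of a female pig aged 23 days was made into cDNA, divided into 2 aliquots, labelled and hybridised together, to assess the background of the array. The labels describe the second array as a repeat of the first and do not say whether it used the same animal or the same RNA. All p-values therefore measure the spread between these 2 hybridisations, or between spots, which may be technical, and no spread between animals was measured.

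The deposited values were 1 signed log2 ratio of the channels per spot and array, for 3888 spots on each of the 2 arrays, with 0 empty entries. The scanner, the dyes, the direction of the ratio, the background correction and the normalization were not given in the sources used here. Both columns had a median of 0, but without spots at exactly 0 on either array the medians were 0.00037 and 0.0070, and over spots 1 to 2595 0.016 and 0.021, so whether the authors centred the arrays stays unknown. The log base was not stated. The largest absolute value was 6.20, above the 4.82 that log10 of the full range of a 16-bit scanner allows, which argued against log10. The values were read as log2, the usual base for 2-colour arrays, while a natural log was not excluded, in which case every fold given here would be larger. Spot brightness was not used here, so no filter on dim spots and no brightness-dependent correction could be made. On array 1, 544 spots had a value of exactly 0, and on array 2, 494 spots. Their number argues against measured ratios for most of them, as given under the other observations. Whether they are missing or flagged ratios entered as 0 is unknown, and medians, SDs and gene means that include them depend on this. They were kept in the main analysis and left out in an alternative.

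Gene names came from the platform's annotation table, which gave 1 gene symbol for 249 spots, several symbols for 0 spots and none for the other 3639. The named spots formed 83 runs of 3 consecutive spot numbers, each run with 1 clone accession and 1 gene. Of the 83 gene identifiers, 80 were found in a table of the pig RefSeq genes, where 0 symbols differed; the other 3 kept the annotation's symbol. Coordinates were not used here, as no genome build goes with the array. The last named spot was number 2595, and this number, taken from the annotation and not from the ratios, divided the spot order into spots 1 to 2595 and spots 2596 to 3888. What was printed at the unnamed spots was not used here.

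From the log2 ratios, the median, SD, robust SD (median absolute deviation scaled to a normal SD) and the 2.5 and 97.5 percentiles were computed on each array. Spots beyond 2-fold (an absolute log2 ratio over 1) were counted, compared between the arrays with an exact two-sided McNemar test, and their overlap was compared with independent lists by a two-sided Fisher's exact test. Pearson's r and Spearman's rho between the arrays were taken across spots, with two-sided permutation tests of 100000 pairings; spots, and the 3 spots of a clone above all, are not independent replicates. The mean log2 ratio of each spot was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes), with 1 residual degree of freedom per spot and Benjamini-Hochberg adjustment at 0.05. The same fit at 1 value per named gene, the mean of its 3 spots, was an alternative set before the data were examined, and it gives every adjusted p quoted for a gene. Repeatability was given as the within-spot SD (the SD of the difference between arrays over the square root of the number of arrays) and as the covariance of the arrays over their mean variance. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

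The limma fit was tested on simulated data with 2 arrays, whose noise took each run's own spread from the real differences between arrays. Over all 3888 spots the fit called 0 of 100 spots changed by 1 on the log2 scale and 0 of 100 changed by 0.5, so a count of 0 from that fit carries no information on shifts of this size. Over spots 1 to 2595 it called 100 of 100 and 79 of 100, with 12 unchanged spots called beside them. For 83 genes with equal noise it called 10 of 10 and 10 of 10. The same noise, drawn 1000 times without any change, gave at least the measured 16 spots beyond 2-fold on both arrays in all 1000 draws over all spots (median 49). The overlap expected from the counts on each array was 3.61 in the draw used to test limma, against 4.21 in the data. The simulated noise, with 1 spread per run for both arrays, thus put large ratios on the same spots more often than the data did. What this means for recovery by the fit over all spots was not tested. Over spots 1 to 2595 the median was 1, against 0 measured. Ranges of r and rho were therefore also taken with the sign of array 2 turned at random for each run of 3 spots, 10000 times.

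The 12 gene lists tested were fixed before the data were examined: neuron, astrocyte, oligodendrocyte and myelin, microglia, endothelium and blood, choroid plexus and ependyma, ribosomal proteins, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, cytoskeleton, reference genes, and stress and immediate early genes. For lists with at least 3 measured genes, the median over the list's spots was placed among 10000 random lists with as many of the 83 genes. The genes and spots named in the text were chosen by a rule fixed at the same time: the spots past the limma threshold or, as none passed, those beyond 2-fold on both arrays in 1 direction, with at most 2 unnamed spots in each direction; the 3 highest and 3 lowest named spots on each array; and, in each list of at least 3 genes, the 2 with the largest and the 1 with the smallest absolute mean, plus the measured reference genes. The genes called at 1 value per gene, genes of the shorter lists, ATP1B1 and DBI were named beyond this rule after their values were seen.

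Alternatives changed the centring, the spread of the arrays, extreme spots, the orientation of array 2, the fold threshold, the variance model, the unit (gene or run of 3 spots), the spots at exactly 0 and the part of the spot order; each array was also taken alone. The number of arrays, 2, limits the precision of every value.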

Results

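Two-colour hybridisation was used to measure how far the channels of a porcine brain cDNA array differ when both hold the same sample. For each array, whole brain cDNA of a young female pig was divided into aliquots, and these were labelled and hybridised against each other. The second array repeated the first, without a statement whether the animal or the RNA was the same. The 2 arrays form 1 group, and the comparison in each is between the channels. Each array gave 3888 log2 ratios, of which 249 belonged to 83 named genes with 3 spots each. The dyes were not given, so a positive ratio is higher in one channel and a negative ratio higher in the other, without saying which. Pearson's r between the arrays was not negative over all spots, at 0.068.

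Among the 83 named genes, the largest mean log2 ratio was 0.23 in size, a 1.17-fold difference between channels, and the median size was 0.075, or 1.05-fold. The highest mean belonged to C1QB, a chain of complement C1q made in brain mainly by microglia, at 0.23 ± 0.13 (SD, n = 2). It was followed by RTCB, the RNA ligase of tRNA splicing, at 0.21 ± 0.14, and COX6B, a subunit of cytochrome c oxidase, at 0.21 ± 0.24. At the other end were CPE, the carboxypeptidase that matures neuropeptides, at -0.22 ± 0.024, and TPT1, which encodes the translationally controlled tumour protein, at -0.21 ± 0.12. In limma at 1 value per gene, these 5 genes (3 positive, 2 negative) passed the threshold, each with an adjusted p of 0.049, and the other 78 did not. The moderation gave the spread shared by all genes a weight of 237.9 degrees of freedom, against 1 for a gene's own. Each gene was thus in effect tested against a common SD of 0.095, and COX6B passed with 0.039 on array 1 and 0.38 on array 2. The calls did not hold under most small changes of the fit. With each array centred on the median of spots 1 to 2595, or on that of the named genes, 0 of the 83 genes passed, while the ratios moved little. C1QB then had a mean of 0.21 and 0.24 (adjusted p = 0.33 and 0.25) and CPE of -0.23 and -0.21 (the same adjusted p). No gene passed either with equal spread on both arrays, with the median of the 3 spots or without moderation. The median of the 3 spots lowered C1QB to 0.17, below COX6B at 0.21 and RTCB at 0.18. The spots of C1QB on array 2 ranged from 0.17 to 0.61. Robust eBayes kept 4 of the 5, all but COX6B, each with an adjusted p of 0.042. With the sign of array 2 turned, none of the 5 passed. This says little, as each had the same sign on both arrays and turning 1 array pulls such means toward 0.

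Ratios of the named genes nevertheless tended to recur. On both arrays 24 genes were positive and 33 negative, so that 57 of 83 genes (68.7%) kept their sign (exact two-sided binomial test against 50%, p = 0.00088, genes not being independent replicates). ATP1B1, the beta subunit of the sodium pump, had log2 ratios of -0.18 on array 1 and -0.21 on array 2. HSPA5, the chaperone of the endoplasmic reticulum, had -0.14 and -0.14. DBI, the acyl-CoA binding protein, had 0.10 and 0.11, and SDHD, a membrane subunit of succinate dehydrogenase, 0.16 and 0.14. These 4 genes, whose arrays agreed closely, did not pass the limma threshold. Of the 83 genes, 26 did not keep their sign, among them SCD (-0.12 and 0.22) and RPS26 (-0.12 and 0.11). The 26 include YWHAZ (-0.30 and exactly 0), which had no sign on array 2 but was counted as not kept, also in the binomial test. Pearson's r across the 83 genes was 0.24 (permutation p = 0.030) and Spearman's rho 0.49 (permutation p = 1e-05, the smallest the pairings can give). TUBB, a beta tubulin, lowered r: without it, r was 0.52 and rho 0.55.

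TUBB and YWHAZ, which encodes a 14-3-3 protein often used as a reference gene, held the named spots farthest from 0. On array 1 the lowest named spots were 1 spot of YWHAZ at -1.84, 1 of TUBB at -1.56 and 1 of CPE at -0.29. The highest named spots on array 1 were another spot of YWHAZ at 0.96, another of TUBB at 0.31 and 1 of HSP90AA1, the cytosolic chaperone, at 0.24. On array 2 the highest were 2 spots of TUBB at 1.18 and 0.62 and 1 of C1QB at 0.61, and the lowest 1 spot each of DESI2 at -0.44, NDN (necdin) at -0.42 and RPS29 at -0.41. YWHAZ was listed at exactly 0 in 3 of 3 spots on array 2, and TUBB in 1 of 3 spots on each array. The SD over the 3 spots was 1.42 for YWHAZ on array 1, against a median of 0.041 over the 83 genes, and 0.59 for TUBB on array 2, against 0.090. B2M, the other measured reference gene, stood at 0.061 on array 1 and 0.081 on array 2.

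**Figure D1:**
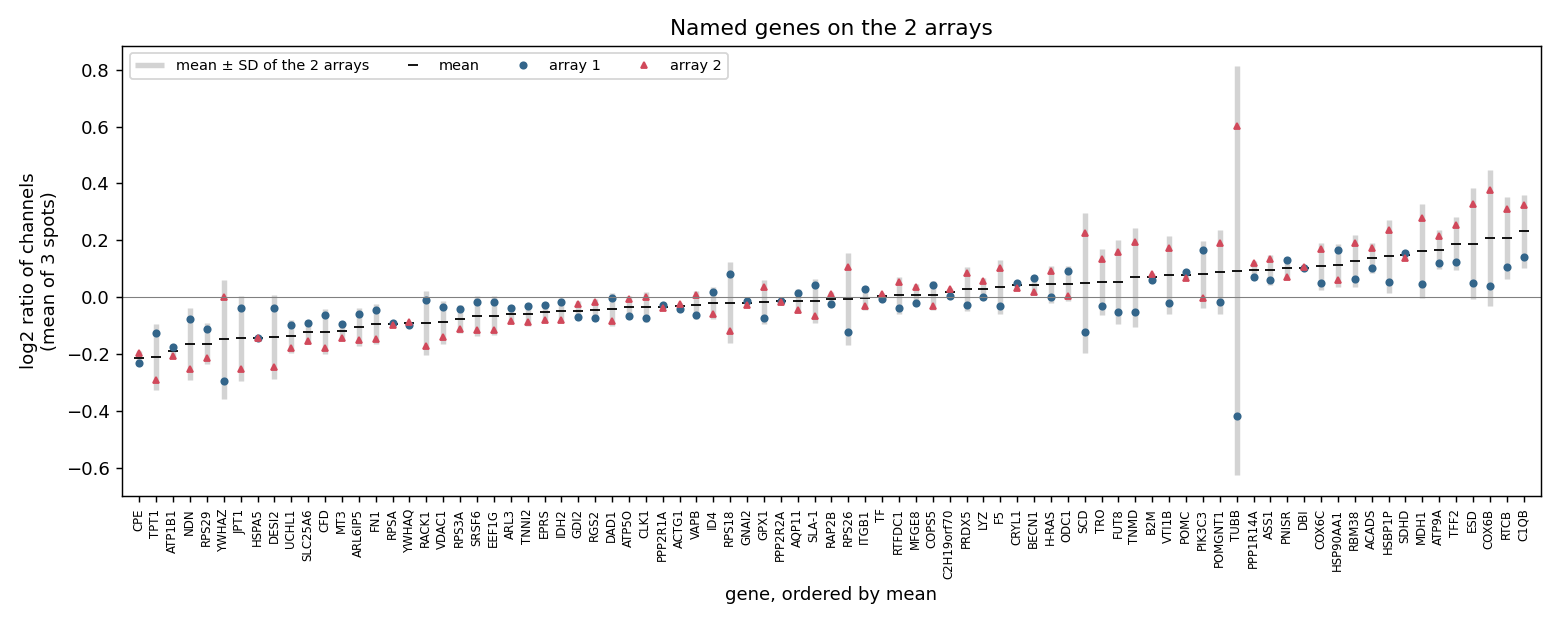
Log2 ratio of the channels (vertical axis) for the 83 named genes (horizontal axis, ordered by their mean), as the mean of 3 spots on array 1 (circles) and array 2 (triangles), with black dashes for the mean of the 2 arrays and grey bars for ± 1 SD (n = 2). The means lie between -0.22 and 0.23, and TUBB has the longest bar (SD 0.72), with -0.42 on array 1 and 0.60 on array 2.

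Of the gene lists, nuclear-encoded oxidative phosphorylation and ribosomal proteins had at least 3 measured genes. The 4 oxidative phosphorylation genes had a median log2 ratio over their 12 spots of 0.12, with 0.046 on array 1 and 0.16 on array 2, at the 97.9th percentile of random lists of 4 genes. COX6B passed the limma threshold (1 gene, also 1 when adjusted over the list alone). COX6C stood at 0.11 ± 0.084, SDHD at 0.15 ± 0.013 and ATP5O, an ATP synthase subunit, at -0.036 ± 0.040 (SD, n = 2), and these did not pass. The 5 ribosomal protein genes had a median of -0.069, with -0.066 on array 1 and -0.097 on array 2, at the 10th percentile of random lists of 5 genes. None of the 5 passed, nor when adjusted over the list alone; RPS29 stood at -0.16 ± 0.072, RPSA at -0.094 ± 0.0046 and RPS26 at -0.0069 ± 0.16. Percentiles describe these 2 arrays and are not tests across animals.

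Markers of brain cell types were few. The neuronal genes CPE and UCHL1, a deubiquitinase abundant in neurons, stood at -0.22 ± 0.024 and -0.14 ± 0.058; 1 passed, and 2 when adjusted over the list alone. MT3, the brain metallothionein of the astrocyte list, stood at -0.12 ± 0.035 and did not pass. For the myelin list, SCD, a fatty acid desaturase, stood at 0.050 ± 0.25 and TF (transferrin) at 0.0026 ± 0.012, neither of which passed. On the microglia list, C1QB passed and B2M, at 0.071 ± 0.015, did not, also when adjusted over the list alone. Neither cytoskeletal gene passed (TUBB at 0.092 ± 0.72, ACTG1 at -0.032 ± 0.011), nor either stress gene (HSP90AA1 at 0.11 ± 0.075, HSPA5 at -0.14 ± 0.0011), nor either reference gene (B2M, and YWHAZ at -0.15 ± 0.21, of which 4 of 6 values were exact zeros; without them YWHAZ stood at -0.44, from 2 spots of array 1 alone). No named gene belonged to the lists for endothelium and blood, choroid plexus and ependyma, or mitochondrially encoded genes.

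Over all 3888 spots, the log2 ratios had an SD of 0.38 on array 1 and 0.46 on array 2 (0.42 ± 0.059, SD, n = 2) around a median of 0, whereas the robust SD was 0.10 and 0.16. The central 95% of spots lay between -0.59 and 0.61 on array 1 and between -0.85 and 0.90 on array 2. The SD and the outer percentiles depended on the place in the spot order. The robust SD was 0.10 on array 1 and 0.17 on array 2 for spots 1 to 2595, and 0.11 and 0.12 for the others, where exact zeros lower it. Spots 1 to 2595, the part that holds the named genes, had an SD of 0.15 on array 1 and 0.20 on array 2; 95% of them lay within 1.16-fold and 1.28-fold, respectively. The remaining 1293 spots had an SD of 0.62 and 0.74, and 95% lay within 2.60-fold and 2.98-fold. Exact zeros followed the same division: 6 and 13 spots among spots 1 to 2595 on arrays 1 and 2, but 538 (41.6%) and 481 (37.2%) among the others. The longest stretch above spot 2595 without an exact 0 and with every ratio under 0.5 in size was spots 3127 to 3237, 111 in number, a rule chosen after the values were seen.

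**Figure D2:**
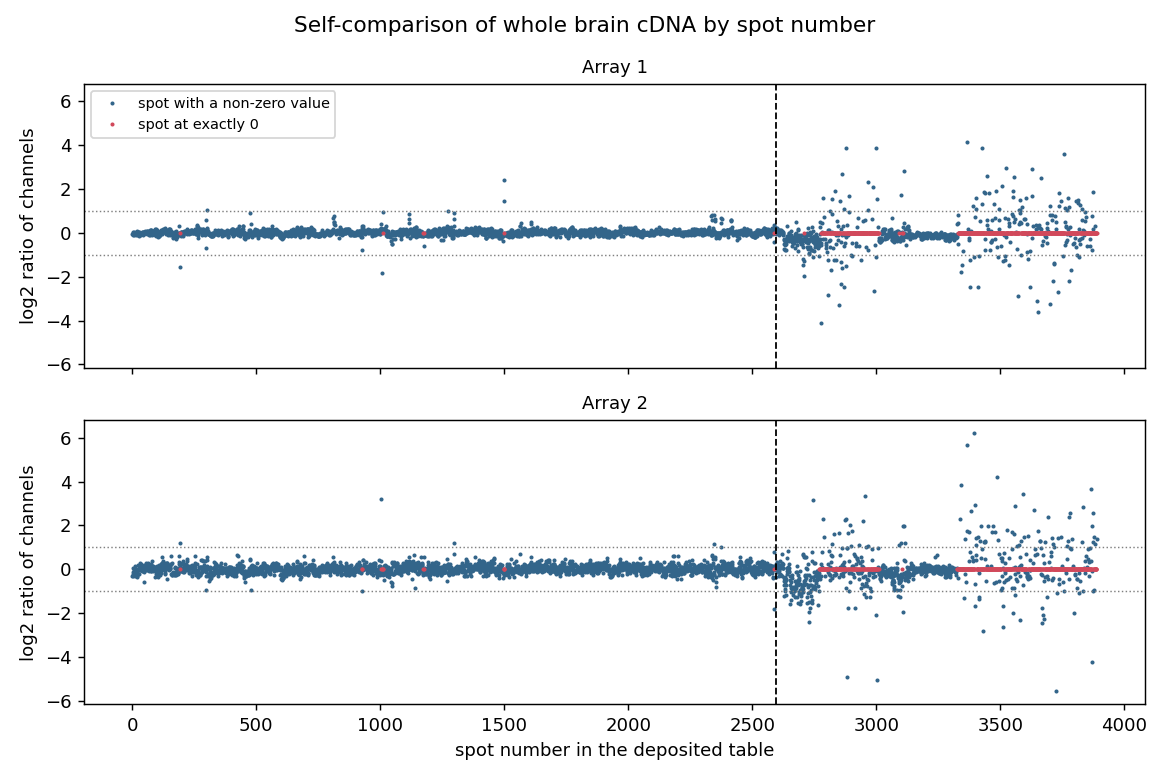
Log2 ratio of the channels (vertical axis) against spot number (horizontal axis) on array 1 (top) and array 2 (bottom); red points are spots at exactly 0, dotted lines mark 2-fold, and the dashed line follows the last named spot, number 2595. Spots beyond the dashed line scatter with an SD of 0.62 and 0.74 and hold most of the exact zeros.

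Beyond 2-fold lay 113 spots (2.91%) on array 1, of which 60 were positive and 53 negative, and 145 spots (3.73%) on array 2, of which 83 were positive and 62 negative. Of spots beyond 2-fold on a single array, 97 were on array 1 and 129 on array 2 (exact two-sided McNemar test, p = 0.039). With the spread of the arrays made equal, array 2 had 28 fewer than array 1 (exact p = 0.062). Spots 1 to 2595 contributed 6 on array 1 and 5 on array 2. Among the named spots these were 2 on array 1, 1 each of YWHAZ and TUBB, and 1 of TUBB on array 2.

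On both arrays, 16 spots were beyond 2-fold, against 4.21 for independent lists (two-sided Fisher's exact test, p = 3.0e-06). All 16 had numbers above 2595, where 11.6 were expected (Fisher's exact p = 0.15). Their directions were evenly divided, 8 the same and 8 opposite, with 2.13 and 2.09 expected. By sign on arrays 1 and 2, 5 were positive on both (1.28 expected, Fisher's exact p = 0.0086), 3 negative on both (0.85 expected, p = 0.051), 7 negative then positive (1.13 expected, p = 0.00011) and 1 positive then negative (0.96 expected, p = 0.62). These expectations take all 3888 spots as equally noisy; above spot 2595, where all 16 lay, 5.83 with the same and 5.76 with opposite directions were expected. Of the 8 with 1 direction, spots 3113 (2.81 and 1.98) and 3743 (1.47 and 1.45) were the highest by their smaller ratio, and spots 3510 (-1.27 and -1.66) and 3415 (-1.05 and -1.25) the lowest; these carry no gene name.

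Across all 3888 spots, Pearson's r between the arrays was 0.068 (permutation p = 0.00029) and Spearman's rho 0.35 (permutation p = 1e-05). Within spots 1 to 2595, r was 0.35 and rho 0.40 (both permutation p = 1e-05). Within the remaining spots, r was 0.027 (permutation p = 0.32) and rho 0.22 (permutation p = 1e-05). That permutation treats all spots as equally noisy, which they were not. With the sign of array 2 turned at random for each run of 3 spots, 10000 times, which keeps the size of every ratio, the central 95% of r lay between -0.056 and 0.058 over all spots (permutation p = 0.021 for the measured r), between -0.088 and 0.089 for spots 1 to 2595, where 0 draws reached the measured r, and between -0.062 and 0.064 for the others (permutation p = 0.41). In none of the 3 did a draw reach the measured rho. The turning takes runs as independent, whereas spots 2596 to 2777 were shifted one way on both arrays (medians -0.28 and -0.44). Where those spots are included, the draws do not separate recurrence spot by spot from this shared shift. In 1000 simulations of normal noise with each run's own spread, r lay between -0.12 and 0.12 over all spots, a range that includes 0.068, and between -0.14 and 0.14 for spots 1 to 2595 (0.20 in the single draw used to test limma). Over all spots these simulations put large ratios on the same spots more often than the data did (37 to 60 beyond 2-fold on both arrays, against 16 measured). Their range of r there therefore does not place 0.068. Both sets of draws were added after r had been seen. After Benjamini-Hochberg adjustment over the 8 correlations, those of the 83 genes included, the permutation p was 0.000387 for r over all spots, 0.0346 for r over genes, 0.32 for r above spot 2595 and 1.6e-05 for the others. The within-spot SD was 0.41 over all spots, with a 95% bootstrap interval over runs of 0.37 to 0.45, and 6.66% of the variance (1.03% to 12.7%) was shared by the arrays. For spots 1 to 2595 these values were 0.14 and 33.3%, and for the others 0.67 and 2.69%.

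**Figure D3:**
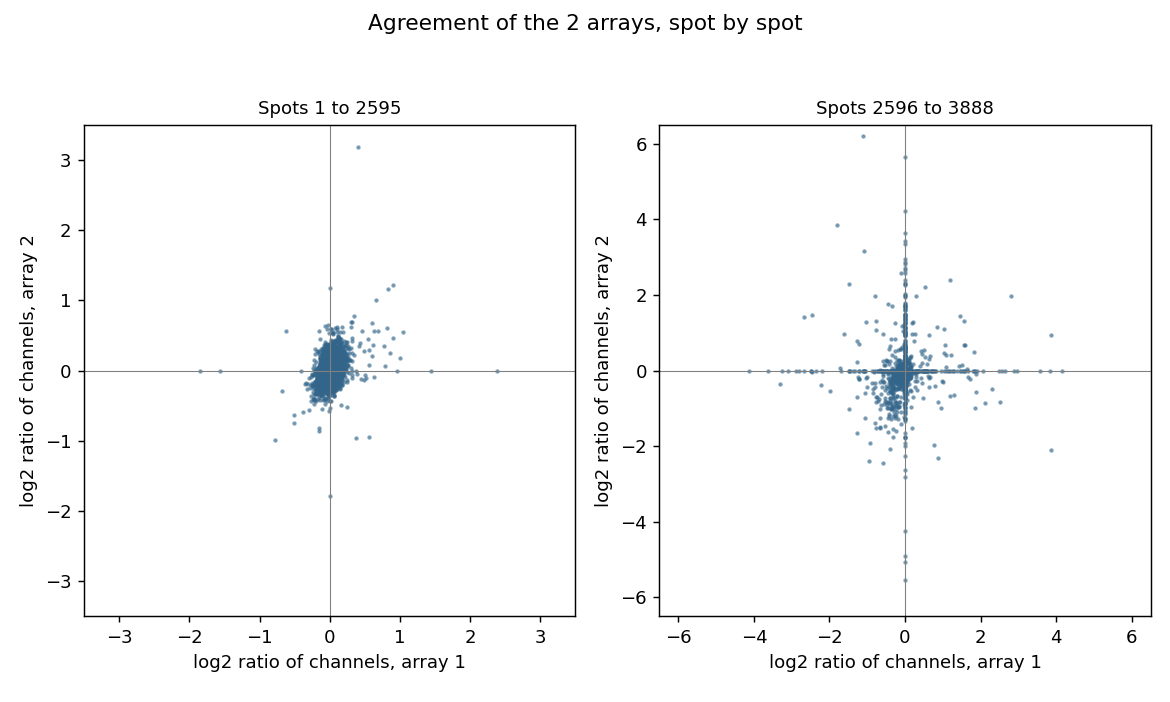
Log2 ratio of each spot on array 1 (horizontal axis) and array 2 (vertical axis), for spots 1 to 2595 (left) and 2596 to 3888 (right), with wider axes on the right. Points on the left lean along the diagonal (r = 0.35), and many on the right lie on an axis because 1 array has an exact 0 (r = 0.027).

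In limma over all 3888 spots, 0 had a mean log2 ratio different from 0 at an adjusted p of 0.05; the lowest adjusted p was 0.46. At an unadjusted p under 0.05 there were 412 spots, against 194.4 expected if every p were uniform. With each array centred on its mean (-0.0025 and 0.0084) there were 284, so this count depends on small offsets of the arrays. Robust eBayes and the t statistic without moderation also called 0, with 436 and 219 at an unadjusted p under 0.05. Within spots 1 to 2595 the count was 0 as well, with 308 at an unadjusted p under 0.05 against 129.75 expected. The fit over all spots recovered 0 of 100 simulated shifts of 1 on the log2 scale, so its count of 0 does not bound shifts of that size; the fit over spots 1 to 2595 recovered 100 of 100.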

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

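No paired analysis was possible because the series holds 1 group. Some settings were added after seeing the data: leaving out spots at exactly 0, taking either part of the spot order, averaging runs of 3 spots, and the alternatives to the fit of 83 genes other than that fit itself. The robust SD moved by less than the spread between arrays (an SD of 0.040, from 2 arrays) under all 10 of its alternatives. Centring on the mean and equal spread leave it unchanged by construction. An array taken alone cannot move it by more than that spread, so these alternatives do not test it. Above spot 2595, however, 41.6% and 37.2% of spots were exact zeros, which lower it, so its 0.11 and 0.12 there do not describe the scatter of the non-zero spots. The SD of 0.42 became 0.29 without the outermost 0.5% of spots, 0.13 at 1 value per gene, 0.32 without exact zeros, 0.17 for spots 1 to 2595, 0.68 for the others and 0.27 for runs of 3; in the same order the within-spot SD of 0.41 became 0.26, 0.12, 0.30, 0.14, 0.67 and 0.25. The shared variance of 6.66% became 21.0%, 20.9%, 13.6% and 33.3% under the first 4, and 16.7% for runs. Arrays taken alone had an SD of 0.38 to 0.46. The mean count beyond 2-fold, 129, became 0 at 1 value per gene, 64.5 without exact zeros, 5.5 for spots 1 to 2595, 18 for runs, 242.5 at 1.5-fold and 59.5 at 3-fold. The excess of 32 such spots on array 2 became 0 (p = 1) at 1 value per gene and for runs, 11 (p = 0.31) without exact zeros and 15 (p = 0.19) at 3-fold, but 85 (p = 9.0e-06) at 1.5-fold; it turned to -28 with equal spread and to -1 (p = 1) for spots 1 to 2595. The overlap beyond 2-fold, 3.80 times that of independent lists, became 8 for runs (2 runs), 0 (0 spots, 0.012 expected) for spots 1 to 2595, 1.38 for the others (Fisher's exact p = 0.15) and 3.35 at 3-fold (Fisher's exact p = 0.059). Much of the excess thus came from taking noisy and quiet spots together. Above spot 2595 the overlap was not told apart from that of independent lists, and no cause for it was tested. The ratio was 12.3 without exact zeros (Fisher's exact p = 2.6e-14), but a spot at 0 on either array cannot be beyond 2-fold on both. Leaving such spots out kept the 16 and lowered the counts from 113 and 145 to 59 and 70, so this rise does not show a stronger overlap. Turning array 2 reversed r to -0.068 and rho to -0.35 by construction; r was 0.22 without the outermost 0.5% of spots, 0.32 without spots beyond 2-fold, 0.14 without exact zeros, 0.17 for runs, 0.35 for spots 1 to 2595 and 0.027 for the others. The spot-level limma count of 0 held under 10 of 11 alternatives, with 56 to 496 spots at an unadjusted p under 0.05. As the fit over all spots recovered 0 of 100 simulated shifts of 1, this does not show that the count is robust. At 1 value per gene the count was 5, where 20 had an unadjusted p under 0.05 against 4.15 by chance. Those 5 fell to 0 with either centring given in the report, equal spread, the median of 3 spots, or no moderation. Leaving out exact zeros kept 0 of the 5 and called 1 gene, YWHAZ, which then had values on array 1 alone (2 spots) and so no spread between arrays. That call is not a result. Turning array 2 called 1 (TUBB, adjusted p = 0.00038), which had opposite signs on the arrays, and kept 0 of the 5, which had the same sign on both, so this setting does not test the calls. Robust eBayes kept 4, without COX6B. The adjusted p of C1QB was 0.99 with array 2 turned, and over the other settings it ranged from 0.042 to 0.67. With array 2 turned, the list medians became 0.044 (ribosomal proteins) and -0.038 (oxidative phosphorylation); array by array the ribosomal median was -0.097 to -0.066. Brightness over background, which limits all ratios, was not used here.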

Other observations

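The tests of dim spots and of the spot order were chosen after the results they bear on had been seen; that of the clones was set before. A test of the exact zeros set before, and one over all spots that replaced it, were left out as tests because the zeros themselves fixed their outcome, and the number of zeros is given below as a description. In these tests both channels held the same sample, so no biological explanation was tested for either pattern.

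Scatter and exact zeros lay mostly above the last named spot. Of the 277 runs of 3 spots with at least 1 exact 0, 270 lay there, among 431 runs. Non-zero spots in runs with a zero had an SD of 1.26 on array 1 and 1.30 on array 2, against 0.29 and 0.51 in runs without a zero above spot 2595 (0.18 and 0.28 over all runs without). A candidate explanation is spots with little hybridised signal: the 130 spots of those runs with a value on both arrays had a between-array r of -0.13 (95% interval -0.29 to 0.045), whereas spots above number 2595 in runs without a zero had r = 0.24 (171 spots, numbers 2596 to 2777) and 0.25 (312 later spots), though 0.12 in the 111 spots of the quiet stretch 3127 to 3237. The 1038 exact zeros of both arrays were 29.9 times the 34.7 values within 0.001 of 0 that ratios of 0.001 to 0.05 in size predict. This argues against measured ratios on a continuous scale for most of the zeros. Whether they stand for missing or flagged ratios was not tested. A brightness per spot, not used here, would bear on that and on the scatter.

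At spots 1 to 2595, log2 ratios recurred on both arrays. A position effect along the spot order was argued against: consecutive spots of different runs correlated at 0.018 on array 1 and 0.022 on array 2 (upper 95% limits 0.084 and 0.088), while neighbours within a run correlated at 0.51 and 0.44. Without the 11 runs holding a zero or a spot beyond 2-fold, the values were 0.048 and 0.037 across runs, without an interval computed, and 0.76 and 0.53 within a run. Position on the slide was not tested. A channel bias of the printed clone remains a hypothesis that went with the values: run means correlated between arrays at 0.47 and deviations from the run mean at 0.13, a difference of 0.34 (95% bootstrap interval 0.21 to 0.47). With the same 11 runs left out, run means correlated at 0.53 and deviations from them at 0.064. Whether it comes from the clone's sequence, its brightness or its printing was not tested.

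Averaging the 3 spots of a run lowered the SD less than independent spots would: from 0.15 to 0.12 on array 1, where 0.084 would follow from independence, and from 0.20 to 0.16 on array 2, against 0.12.

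Spots 2596 to 2777, up to the first spot at exactly 0 on both arrays, a stretch chosen after its values were seen, were shifted one way on both arrays: 147 of 182 were negative on array 1 (median -0.28) and 132 on array 2 (median -0.44).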
